A study of Mus musculus with 4 samples.

How the data were processed

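Transcripts were measured by RNA-seq in mouse embryonic stem cells that carry a tamoxifen-inducible Cre recombinase (Rosa26CreER), 1 conditional (floxed) Chd1 allele and 1 null allele. Per the labels' protocols, cells of 2 independently derived lines were treated with ethanol (control) or 1 µM tamoxifen (Chd1-null) for 48 to 72 h. They were then grown without tamoxifen for 3 to 5 passages in serum with LIF. The control cells therefore carry 1 functional allele. Total RNA came from equal numbers of viable cells. Per the labels' protocols, equal volumes of eluted RNA, of about 1 µg, received 1 µL of a 1:10 dilution of a mix of 92 synthetic ERCC transcripts, so that amounts can be compared per cell. Ribosomal RNA was depleted, strand-specific libraries were made, and paired reads of 100 bases were obtained on 2 lanes. The labels name set 1 and set 2, each with 1 control and 1 Chd1-null library, so each group had n = 2. They do not tie a set to a line in words.

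The deposited values were taken as FPKM, fragment numbers scaled to transcript length and sequencing depth, with 1 table per set. The file headers do not write the unit. It was inferred from the submitters' processing notes, which name TopHat2 2.0.10, TopHat, Cufflinks 2.2.0, Cuffdiff and the mouse build mm9, and from the values, which are not whole and whose column sums differ. The step each tool did, the annotation, and the way the ERCC transcripts entered the scaling are not given in the sources used here. ERCC transcripts were not analysed here. A change per cell below therefore rests on the scaling of the deposited values. Each table also holds a deposited ratio of Chd1-null over control, which equalled the quotient of the value columns beside it to within a relative difference of 4.97e-06. The lowest value was 0.100 in both tables, so loci under that level in either library were not analysed here. Read depth is unknown, because FPKM was the unit used, and no counting interval is given.

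Set 1 held 16553 loci and set 2 held 16967. Locus identifiers are numbered separately per set, so genes were joined by symbol. Loci without a gene symbol (3939 and 3866), loci merging several genes (147 and 144) and symbols that occurred more than once in a table (156 and 190 loci) were left out of the joint tests. In all, 11728 genes were named in both sets, and the 10261 with a mean of at least 1 FPKM over the 4 libraries were tested. Another 583 genes were named in set 1 alone and 1039 in set 2 alone. The files give no coordinates, so none are given.

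Values were compared as log2(FPKM + 0.1), a scale that understates the change of low genes. The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend on level), two-sided, with set as a block and Benjamini-Hochberg adjustment at 0.05. Set was the block because each set has its own table and the protocol names 2 lines. Deviations of the control and Chd1-null library of a set from their group means correlated across genes (r = 0.483). With 2 pairs the fit has 1 residual degree of freedom, so each test leans on the variance that limma estimates from all genes (prior degrees of freedom Inf). The absolute comparison used the values as deposited. The relative comparison first subtracted each set's median log2 ratio. With prior degrees of freedom of Inf, p-values rest on a spread between the 2 sets shared by genes of similar level. A gene's own spread between the sets does not enter them.

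Gene lists, 31 in all, were fixed before the data were examined. The 28 with at least 3 tested members were tested with camera (limma) at a preset correlation of 0.01, and again with an estimated correlation. The preset value was assumed. The second form has 1 degree of freedom here, so a list can hardly pass it, and not passing it decides nothing. Camera compares limma's t-statistics of a list and of other genes, so a list can be lower without a larger median log2 change. Each list's median was also placed among 10000 random lists matched on mean expression in 20 bins. Named genes were chosen by a rule also fixed before the data were examined. It takes Chd1, then the 8 highest and 8 lowest genes by the smaller of their absolute log2 ratios in the 2 sets, in the absolute and in the relative comparison. Those need a mean of at least 5 FPKM and the same sign in both sets, and predicted genes and small RNAs are left out of them. The rule then takes up to 3 members per list with the largest mean change and the same sign in both sets. Genes named outside the rule are said to be so, and 1 gene that the rule takes is not reported here.

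The test was checked on simulated data of 10261 genes with 200 changed genes and 2 pairs, for the relative comparison. Where all genes of a level shared one spread, 78.0% of 2-fold changes were recovered, and 5 of 161 calls were false. With a spread that differed from gene to gene, 0 of the 2-fold changes and 78.0% of 4-fold changes were recovered, the latter with 10 of 166 calls false.

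Alternatives covered the pseudocount, the filter on low values, the block, the variance prior, the scaling, the centring, the correlation within lists and the libraries left out. Removal of each set's trend on expression level (loess, span 0.3) was among those added after seeing the data. Gene class, length and hosted small nucleolar RNAs (snoRNAs) came from GENCODE M21, an annotation of a later build, matched by symbol for 10169 of the 10261 genes (99.1%, of which 434 through an older symbol). Figures were drawn with matplotlib from the same values.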

Results

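RNA abundance per cell was compared between control and Chd1-null mouse embryonic stem cells, the cultured counterpart of the early embryo's pluripotent cells. Chd1 encodes an ATP-dependent chromatin remodeler found at transcribed genes. There were 4 libraries, 1 control and 1 Chd1-null in each of 2 sets. FPKM summed over loci to 584520 in control 1, 466994 in Chd1-null 1, 719549 in control 2 and 518032 in Chd1-null 2. The 10 highest loci took 14.7%, 12.3%, 22.1% and 22.6% of these sums.

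Chd1 itself fell in both sets. It stood at 27.6 FPKM in control 1 and 5.71 in Chd1-null 1, and at 17.9 in control 2 and 8.52 in Chd1-null 2. That left 20.7% of the control value in set 1 and 47.7% in set 2. The log2 fold change was -1.66 with a limma SE of 0.25 (n = 2 pairs, limma adjusted p = 1.8e-08). This SE, like those of genes below, comes from the variance shared by genes of similar level. The log2 ratios of Chd1 in the sets were -2.25 and -1.06 (SD 0.84). The labels do not say which exons are deleted, and the FPKM value covers the whole locus, so the remaining share does not measure functional transcript.

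The first comparison addressed whether cells without Chd1 hold less RNA per cell. Most genes had lower values in Chd1-null cells in both sets. The median gene stood at 0.727 of its control in set 1 (log2 ratio -0.46, quartiles -0.82 and -0.18) and at 0.796 in set 2 (-0.33, quartiles -0.56 and -0.10). The mean of the medians was -0.39 ± 0.09 (SD, n = 2), or 0.761-fold. Of 10261 genes, 87.3% were lower in set 1 and 82.4% in set 2. In both sets 7431 genes were lower (72.4%, against 71.9% for independent sets) and 288 were higher (2.81%), while 2542 went opposite ways. With 2 pairs, the smallest two-sided p of an exact sign-flip test is 0.5, so that test cannot pass at 0.05. With each library divided by its own total, which takes out a change common to all genes by construction, the medians were -0.14 in set 1 and 0.14 in set 2.

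**Figure D1:**
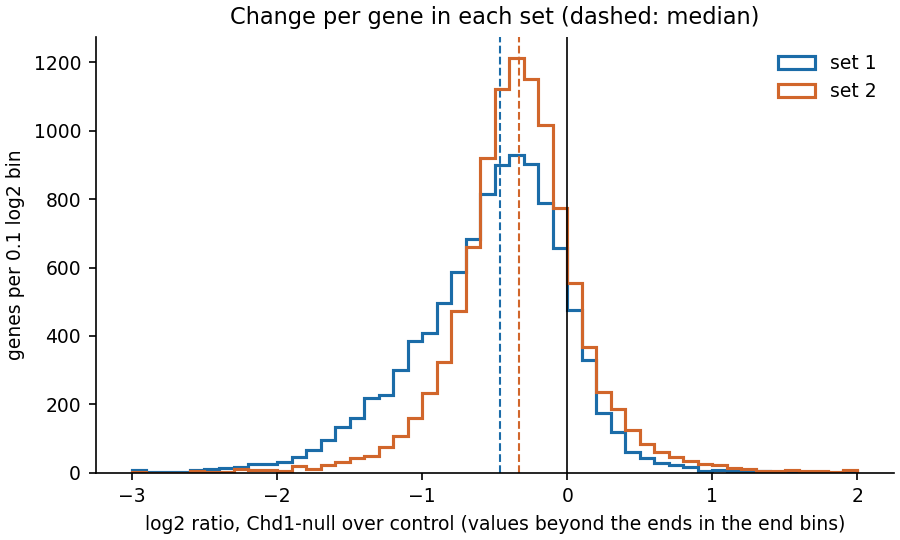
Number of tested genes per bin of 0.1 in the log2 ratio of Chd1-null over control, for set 1 and set 2 (values beyond the axis are in the end bins; dashed lines mark the medians). Both medians lie below 0, at -0.46 in set 1 and -0.33 in set 2.

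Among single genes on the deposited scale, 1006 fell and 7 rose (limma, adjusted p under 0.05). Nupr1, a stress-induced regulator of transcription, fell by 2.2 on the log2 scale (SE 0.36, adjusted p = 5.9e-07), from 10.2 to 1.49 FPKM in set 1 and from 9.76 to 2.95 in set 2. The noncoding RNAs Snhg1 and Dancr, both hosts of small nucleolar RNAs, fell by 1.46 ± 0.17 (SE, adjusted p = 1.1e-13) and by 1.52 ± 0.19 (adjusted p = 2.6e-12). Of the autophagy genes Atg13 and Map1lc3a, the former fell by 1.40 ± 0.34 (adjusted p = 0.0031) and the latter by 1.57 ± 0.35 (adjusted p = 0.00095). Mov10, an RNA helicase, fell by 1.49 ± 0.27 (adjusted p = 7.7e-06). Ldhd, a mitochondrial D-lactate dehydrogenase, fell by 1.97 ± 0.51 (adjusted p = 0.0045), though it stood at 0.683 FPKM in control 1 against 26.6 in control 2. BC052688 fell by 1.47 ± 0.35 (adjusted p = 0.0020).

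Few genes rose. Myl9, a regulatory light chain of myosin, rose from 13.2 to 26.0 FPKM in set 1 and from 5.30 to 13.2 in set 2 (log2 fold change 1.13 ± 0.25, adjusted p = 0.00054). Mrpl52, a protein of the mitochondrial ribosome, rose by 0.90 ± 0.18 (adjusted p = 0.00012), Nhej1, a DNA end-joining factor, by 0.75 ± 0.26 (adjusted p = 0.0445) and the folate receptor Folr1 by 0.60 ± 0.17 (adjusted p = 0.0145). With a pseudocount of 1 Nhej1 narrowly missed the threshold. Of the 7 genes, 2 went opposite ways in the sets: Bmyc (log2 ratios -0.64 and 4.57) and Fam13c (-0.21 and 3.77), both named after their values were seen. Of the 1006 genes, 14 went opposite ways. Wnt8a (log2 fold change 0.90), Endog (0.66) and Rdh14 (0.66) had higher values in both sets without passing the test.

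These counts depend on the variance model, the scaling, the filter on low values and the level trend. With a mean of at least 5 FPKM 2 genes rose and 225 fell, and with each set's level trend removed 3 rose and 298 fell. With one common prior variance 0 genes passed in limma (lowest adjusted p = 0.288, the value of Chd1; 1718 genes at an unadjusted p under 0.05), and without the block again 0 (lowest adjusted p = 0.461, Chd1 included; 1043 unadjusted), against 2995 unadjusted in the main test. In the simulation, made for the relative comparison, one common prior variance recovered 0% of 2-fold changes under either spread. It recovered 94.5% of 4-fold changes with one spread per level and 0% with a spread that differed by gene. A count of 0 under it can therefore arise although genes changed. Scaled to library totals, 50 genes rose and 37 fell.

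The second comparison asked which genes departed from the shift that most genes shared. Relative to each set's median, 22 genes fell and 15 rose. Of the 15, 3 had log2 ratios of opposite sign in the sets before the median was subtracted. Such a gene can still lie above the median in both sets. Chd1 fell by 1.26 beyond the median (limma adjusted p = 0.00081), Nupr1 by 1.80 (adjusted p = 9.3e-05), Dancr by 1.12 (adjusted p = 0.00081), Snhg1 by 1.06 (adjusted p = 0.0033), Snhg6 by 0.86 (adjusted p = 0.0346) and Mov10 by 1.09 (adjusted p = 0.0158). Terc, the RNA of telomerase, fell by 1.02 beyond the median (adjusted p = 0.0072), from 195 to 62.9 FPKM in set 1 and from 230 to 100.3 in set 2. Fam211a fell by 1.12 (adjusted p = 0.0273). Genes that rose included Mrpl52 (relative log2 change 1.30, adjusted p = 2.7e-05), the mitochondrial nuclease Endog (1.05, adjusted p = 0.0172), the complex I subunit Ndufa5 (0.88, adjusted p = 0.0269) and Romo1 (0.85, adjusted p = 0.0390). Myl9 (1.53, adjusted p = 1.4e-05), Nhej1 (1.15, adjusted p = 0.0072), Spin2c (1.17, adjusted p = 0.0331) and Folr1 (0.99, adjusted p = 0.0066) rose as well. With a common prior variance 0 genes passed in limma in this comparison (lowest adjusted p = 0.0731, 614 unadjusted). Without the block, and with each library centred on its own median value instead, 0 passed (lowest adjusted p = 0.9999, 154 unadjusted). The main test had 645 unadjusted.

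**Figure D2:**
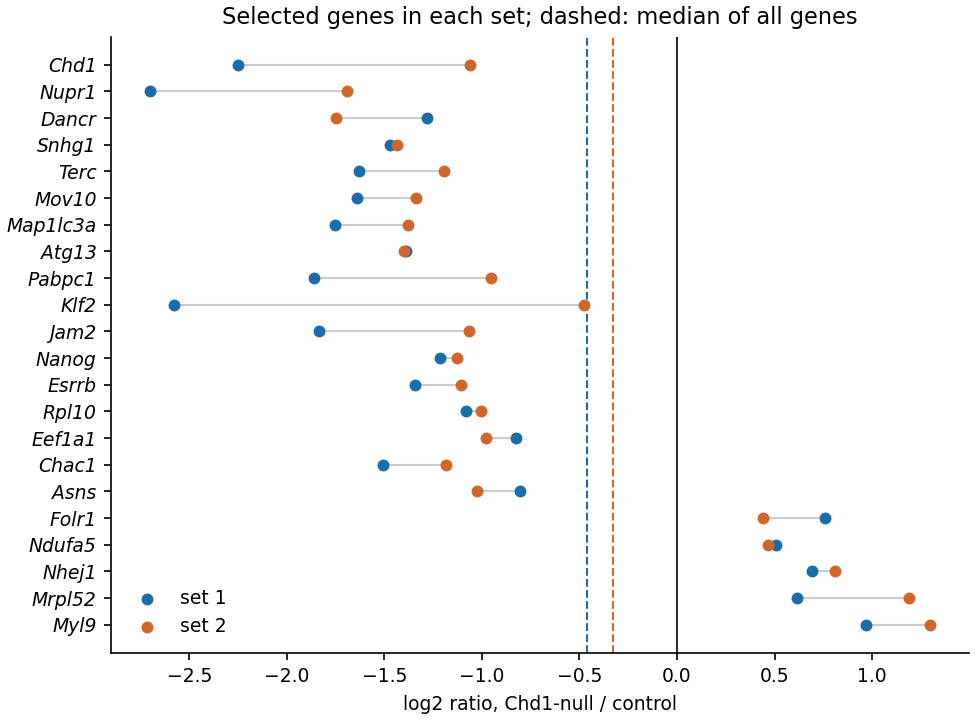
Log2 ratio of Chd1-null over control in set 1 and set 2 for 22 genes (1 point per set; dashed lines mark the medians of all genes; Nanog and Esrrb were chosen after their values were seen). Atg13 and Snhg1 had nearly equal ratios in the sets, while Klf2 stood at -2.58 in set 1 and -0.48 in set 2.

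Of 34 tested pluripotency genes, 31 were lower in both sets, 21 fell and 0 rose over all genes tested (25 fell adjusted over the list alone). The list's median log2 ratio was -0.70 in set 1 and -0.55 in set 2. Klf2, a transcription factor of the naive state, fell by 1.53 (limma SE 0.30, adjusted p = 6.3e-05), mostly in set 1 (log2 ratios -2.58 and -0.48). Jam2, an adhesion molecule, fell by 1.45 ± 0.40 (adjusted p = 0.0087), and Prdm14 had a log2 fold change of -1.39 (adjusted p = 0.0614). Outside the rule, and chosen after their values were seen, Nanog fell by 1.17 (adjusted p = 4.3e-08) and Esrrb by 1.22 (adjusted p = 1.9e-07), while Pou5f1 had a log2 fold change of -0.33 (adjusted p = 0.20). The list was lower than other genes in camera (adjusted p = 6.0e-14, and 1.2e-07 after centring). With an estimated correlation, where 1 degree of freedom means that hardly any list can pass, it did not pass (adjusted p = 0.721). Relative to the median, 1 member fell over all genes; over the list alone 9 fell and 1 rose.

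Targets of ATF4, the transcription factor of the amino-acid and integrated stress response, were the other list below matched random lists in both sets. Of 18 members 9 fell and 0 rose (12 fell adjusted over the list alone), with medians of -0.61 and -0.54. The glutathione-degrading enzyme Chac1 fell by 1.35 ± 0.33 (adjusted p = 0.0025), Pck2 by 1.08 ± 0.29 (adjusted p = 0.0065) and asparagine synthetase Asns by 0.92 ± 0.17 (adjusted p = 2.1e-05). In camera the list was lower (adjusted p = 0.00057, and 0.0431 after centring). With an estimated correlation, which hardly any list can pass here, it did not pass (adjusted p = 0.721). The list medians stood at percentiles 0.690 and 1.84 of the random lists, against 0 and 0.0700 for pluripotency.

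Of 78 cytosolic ribosomal proteins, 66 were lower in both sets, and 19 fell (31 adjusted over the list alone), with medians of -0.25 in set 1 and -0.53 in set 2. Rpl10 fell by 1.05, Rps27 by 0.84 and Rps20 by 0.83; reads of these genes can be shared with many processed pseudogenes, so single values are uncertain. Of 35 translation factors 8 fell (9 over the list alone), and the medians of -0.30 and -0.32 lay above those of all genes in both sets. Pabpc1, the cytoplasmic poly(A)-binding protein, fell by 1.41 and was also lower relative to the median (adjusted p = 0.0209); Eif1 fell by 1.02, mostly in set 1, and the elongation factor Eef1a1 by 0.90. In camera, which compares t-statistics, both lists were lower (adjusted p = 0.0059 and 0.0106), but they were not lower by median log2 change. That median minus the one of all genes was 0.0203 for ribosomal proteins and 0.12 for translation factors. After centring the direction in camera turned to higher (adjusted p = 0.863 for each), and with an estimated correlation neither passed (adjusted p = 0.813 and 0.721). Without the block the translation factors did not pass (adjusted p = 0.160).

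Of 50 ribosome biogenesis genes 5 fell (5 over the list alone), among them the pseudouridine synthase Dkc1 (by 0.63), nucleolin Ncl (by 0.61, mostly in set 1) and Rcl1 (by 0.60). Among 15 RNA polymerase I genes 3 fell (7 over the list alone), including Taf1d (by 0.84) and Znrd1 (by 0.67). Among 35 RNA polymerase II genes 4 fell (4 over the list alone), including Cdc73 (by 0.86, mostly in set 1), Ccnt1 (by 0.64) and Polr2e (by 0.63, mostly in set 2). None of these 3 lists passed camera (adjusted p = 0.225, 0.238 and 0.780).

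Cell cycle genes had lower values in nearly all cases: 30 of 33 G1-S genes and all 26 G2-M genes were lower in both sets. Of these, 7 and 5 fell (15 and 10 over the list alone), such as the replication licensing factor Cdt1 (by 0.98) and the kinase Aurkb (by 0.72). Of 50 replication-dependent histone genes 19 fell (25 over the list alone), with medians of -0.28 and -0.64; Hist2h3c2 fell by 2.46 and Hist1h3d by 1.00, and near-identical copies make single histone values uncertain. Among 34 chromatin regulators 9 fell (15 over the list alone), including the Polycomb proteins Jarid2 (by 0.85) and Suz12 (by 0.85, mostly in set 1). The chromatin medians were -0.67 in set 1 and -0.24 in set 2, at percentiles 0 and 98.3 of matched lists. These 4 lists were lower in camera (adjusted p = 0.0115, 0.0115, 0.00057 and 0.0019). With an estimated correlation, which hardly any list can pass here, they did not pass (adjusted p = 0.721 for each). None passed after centring (adjusted p = 0.704, 0.995, 0.995 and 0.190), and without the block the histones did not (adjusted p = 0.760).

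In metabolism, 8 of 21 glycolysis genes fell (11 over the list alone), for example Aldoc (by 1.17) and Pfkp (by 0.88, mostly in set 1), and camera did not call the list (adjusted p = 0.0663). Of 21 aminoacyl-tRNA synthetases 7 fell (11 over the list alone), among them Wars (by 0.64), Iars (by 0.60) and Cars (by 0.59). Of 61 nuclear genes of oxidative phosphorylation 3 fell (2 over the list alone), 2 of them Uqcrq (by 0.86) and Cox8a (by 0.72, mostly in set 2). The list's medians were -0.01 and -0.35, the latter slightly below the median of all genes, and after centring it was higher than other genes (adjusted p = 1.1e-06; 0.996 with an estimated correlation). The proteasome (2 of 31 fell, 2 over the list alone, Psmd3 and, mostly in set 2, Psma1) was also higher after centring (adjusted p = 0.0014; 0.996 with an estimated correlation). Of 21 genes in the heat shock and chaperone list, which is not of chaperones alone, 5 fell (5 over the list alone). Among them were Hsph1 (by 1.01, mostly in set 1) and Xbp1 (by 1.00). All 14 housekeeping genes were lower in both sets and 6 fell (8 over the list alone), including Tuba1b (by 0.87) and Ppia (by 0.67). The synthetase and housekeeping lists were lower in camera (adjusted p = 0.0043 and 0.0339), but not after centring (adjusted p = 0.995 and 0.863). With an estimated correlation, which hardly any list can pass here, neither passed (adjusted p = 0.721 for each).

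Lists of markers of other lineages were short and held few calls each. Over all tested genes 9.87% were called, so few calls do not set these markers apart. In the primed epiblast list 2 of 16 fell (3 over the list alone), the keratin Krt18 by 0.92. That list's medians of -0.22 and -0.03 lay above those of all genes in both sets. Camera did not call it (adjusted p = 0.143, 0.0588 after centring and 0.721 with an estimated correlation), but did call it higher without the block (adjusted p = 0.0102). Of 12 primitive endoderm genes 2 fell (3 over the list alone), Lama1 by 1.00, mostly in set 1, and Apoe by 0.64, mostly in set 2. Of 12 neural genes 2 fell (2 over the list alone), the tubulin Tubb3 by 1.02. Of 10 trophectoderm genes 1 fell (1 over the list alone). Of 12 germline genes 1 fell (1 over the list alone), Tex19.1 by 0.89. None of 8 fibroblast and feeder markers, 2 mesoderm genes or 1 gene of the totipotent-like state passed over all genes tested in limma. The gene of the totipotent-like state fell over its list alone, which with 1 member means no adjustment. Of 23 imprinted genes 5 fell (9 over the list alone), including Igf2 (by 1.68) and Peg10 (by 1.13, mostly in set 1). Of 26 p53 targets 3 fell (4 over the list alone), among them Zmat3 (by 0.94, mostly in set 1) and Sesn2 (by 0.55, mostly in set 1), yet the list was higher after centring (adjusted p = 0.0415; 0.996 with an estimated correlation). Of 16 apoptosis regulators 1 fell (2 over the list alone). In the CHD family 1 of 8 fell (1 over the list alone), Chd1 itself. The list was lower in camera (adjusted p = 0.0332; 0.721 with an estimated correlation; 0.0731 without the block), but it holds the deleted gene, and its median in set 2 (-0.19) lay above that of all genes. None of 4 X-linked identity genes passed, and mitochondrial genome transcripts were not analysed here.

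**Figure D3:**
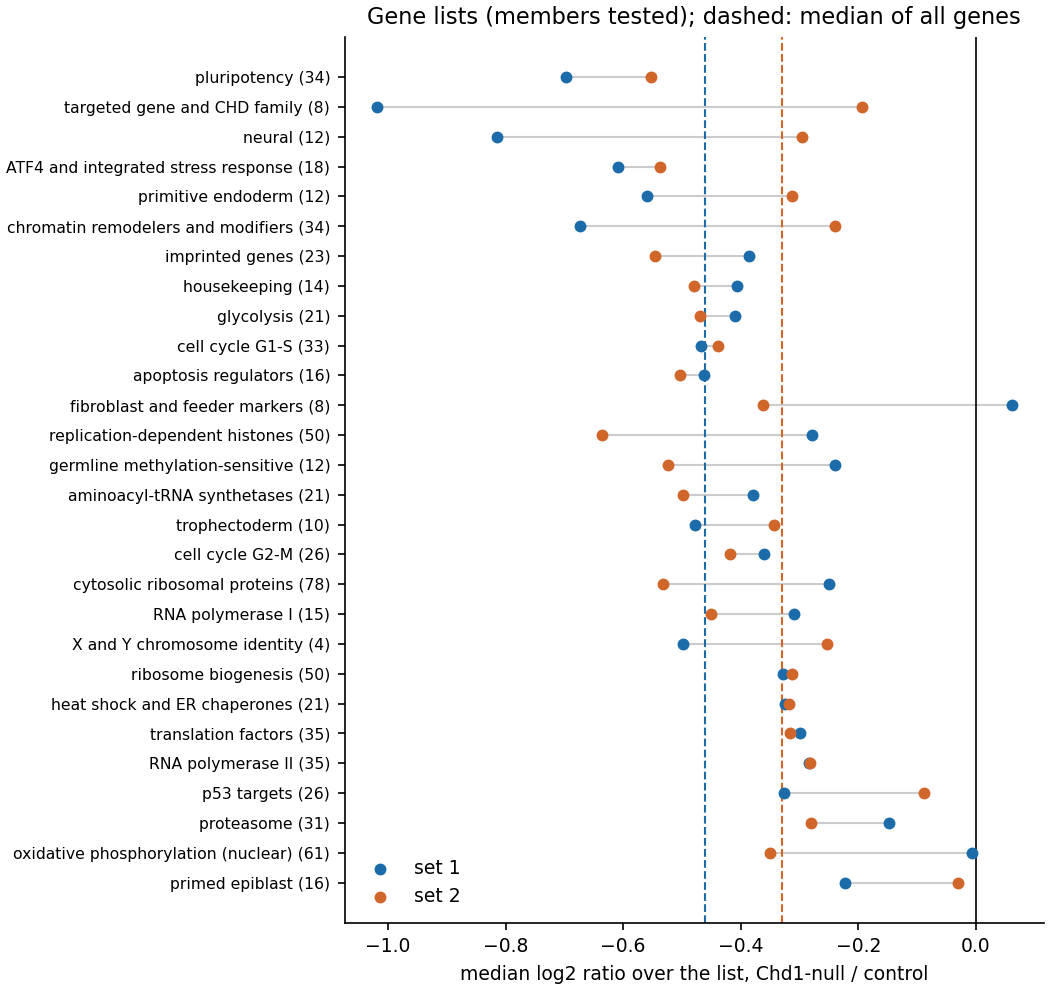
Median log2 ratio of Chd1-null over control for each list with at least 3 tested genes, in set 1 and set 2 (members tested in parentheses; dashed lines mark the medians of all genes). Pluripotency (-0.70 and -0.55) and ATF4 targets (-0.61 and -0.54) lie below the median of all genes in both sets.

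The last comparison asked how far the sets agreed. Across genes, which are not independent replicates, the log2 ratios of the sets had Pearson r = 0.0306 and Spearman rho = 0.00406, and 49.3% of genes lay on the same side of both medians. By a fold limit chosen after seeing the data, 1047 genes were at least 1.5-fold lower in both sets, against 937.9 for independent sets, and 189 were at least 2-fold lower, against 97.4. The change differed with expression level. In set 1 the lowest decile of genes stood at 0.513 of control and the highest at 0.868, whereas in set 2 the same deciles stood at 0.850 and 0.767.

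**Figure D4:**
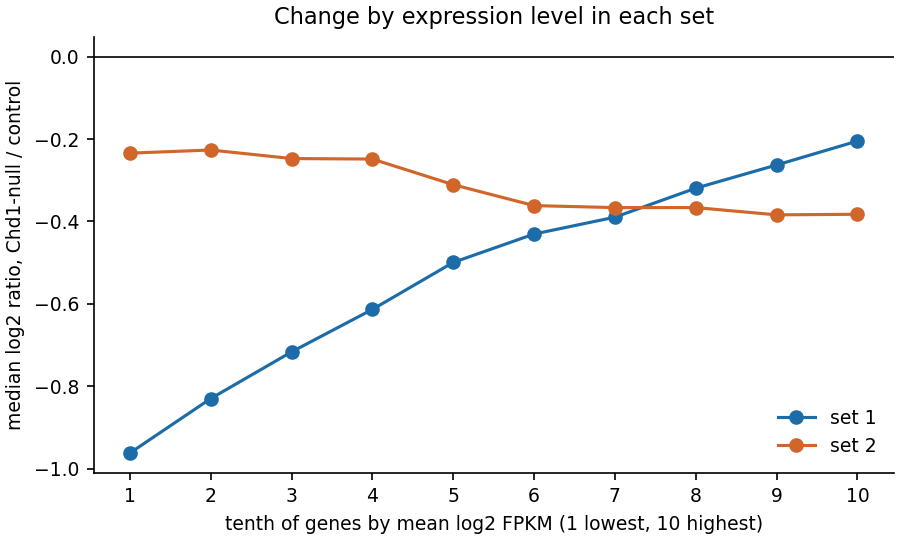
Median log2 ratio of Chd1-null over control per decile of genes ordered by mean log2 FPKM, in set 1 and set 2. From the lowest to the highest decile the median went from -0.96 to -0.20 in set 1 and from -0.23 to -0.38 in set 2.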

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

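Of the tests in this part, those of low-value noise in each set and of length as the whole cause were chosen only after the result was seen.

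The dependence of the change on expression level had opposite signs in the sets. The median log2 ratio of the highest decile of genes minus that of the lowest was 0.76 in set 1 (bootstrap 95% interval over genes 0.71 to 0.82) and -0.15 in set 2 (-0.22 to -0.10). With 1 library pair per set, the difference between the sets was not tested. Noise near the lowest values would vanish among the 4833 genes with a mean of at least 10 FPKM: the difference stayed at 0.25 there in set 1 (interval 0.20 to 0.31), which argues against it as the whole cause, but was -0.0196 in set 2 (interval -0.07 to 0.04), where it may account for the trend. Gene length remains partly open by the bound set beforehand, which asked that at least 80% of the slope stay in both sets once length entered: 89.9% stayed in set 1 and 79.5% in set 2, just short of it. By the later test the slope on level with length included was still 0.0898 (SE 0.0023) in set 1 and -0.0252 (SE 0.0022) in set 2, so length was not the whole cause. Loci without a gene symbol, processed alongside, had slopes of 0.223 in set 1 and -0.143 in set 2. Named genes had slopes of the same signs, 0.0999 and -0.0317. Scaling that differed with level would give the same signs. These loci come from the same libraries, so other causes could give them too, and the test does not tell them apart. A difference between the sets' cells stays open and untested.

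The 8 fibroblast and feeder markers had a median log2 ratio of 0.0617 in set 1 and -0.361 in set 2, and this difference in sign was not tested. Among matched random lists these medians stood at percentiles 99.8 and 33.6.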

How the results depend on the processing

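Removal of the level trend, the counts of genes lower in both sets by a fold limit and, for gene lists, the common prior variance were chosen only after the data were seen. The median shift kept its direction under every alternative run on the deposited scale. Counts of calls did not hold. Absolute calls, higher and lower, were 7 and 1006; with pseudocount 1 higher calls were 4 (899 lower calls were shared), with a mean of at least 5 FPKM they were 2 and 225, with library totals 50 and 37, and with the level trend removed 3 and 298. Relative calls, 15 and 22, became 2 and 3, 26 and 53 when centred on genes with a mean of at least 10, and 4 and 8 with the trend removed. With the common prior variance and with no replicate block all 4 counts were 0. The relative fit without the block also centred each library on its own median value. A pair without its partner cannot stay in the blocked fit, so libraries were left out in turn with no replicate block; those counts (range 0 to 0) say nothing of single libraries. The correlation between sets was -0.0118 without a filter, 0.0849 at a mean of at least 5 and 0.0842 with the trend removed. The level difference was 0.34 and -0.24 with pseudocount 1, and -0.0926 in set 2 with deciles by the other set's mean. Genes lower in both sets numbered 189 at a limit of 2-fold. Lists lower and higher, 11 and 0, became 3 and 3 when centred and 2 and 3 with the trend removed. With the common prior variance they were 1 and 3. By matched random lists 2 were lower, and higher lists numbered 1 with pseudocount 1 and 4 with no replicate block. With an estimated correlation 0 were lower, in a test whose 1 degree of freedom means that hardly any list can pass. The direction of the list test turned from lower to higher for ribosomal proteins when centred, for translation factors when centred or with one common prior variance, and for histones with the latter, none past the threshold; the medians minus that of all genes (0.0203, 0.12 and -0.0270) are as in the main test. Among the 11 lists lower in camera, that difference had opposite signs with set 1 or set 2 left out in 7: CHD family -0.56 to 0.14, ribosomal proteins -0.20 to 0.21, G2-M -0.0896 to 0.10, histones -0.31 to 0.18, synthetases -0.17 to 0.0817, chromatin regulators -0.21 to 0.0902 and housekeeping -0.15 to 0.0547. Of 106 named gene values none reversed. Centring alone could have reversed one, since these genes have the same sign in both sets and the other alternatives cannot turn it. Of the 106, 67 lost their call with no replicate block, 53 when centred, where 4 gained one, and 1 with pseudocount 1. Scaling to ERCC transcripts was not run. The cause was not tested for these changes. Read depth was unknown, so its limit cannot be stated.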

Other observations

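Of the tests in this part, the split by set of the test on protein-coding hosts and both tests on the correlation between sets were chosen only after the result was seen.

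Long noncoding genes that host small nucleolar RNAs, which guide modification of ribosomal RNA, had lower values well beyond the general shift. Of 22 such genes by annotation, a class chosen after several members were seen among the lowest genes, 18 were lower in both sets and 16 fell (limma, adjusted over all genes). The class median log2 ratio was -0.93 in set 1 and -0.85 in set 2. Gas5 fell from 103.6 to 53.2 FPKM in set 1 and from 159 to 88.3 in set 2, Snhg3 fell by 0.92, Snhg5 by 0.96, Snhg8 by 0.85 and Snhg12 by 1.39 (mostly in set 2), while Rian, like these chosen outside the rule, had a log2 fold change of -0.10. Leaving out the hosts named by the rule or past the relative test, the other 17 still had medians of -0.84 and -0.80, below all 10000 matched random lists in both sets, and 11 of them fell. The annotation also counts Cct6a in the class, which encodes a chaperonin subunit.

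Proteins of the mitochondrial ribosome, a class chosen after Mrpl52, one of its members, was seen among the highest genes, had medians over 73 genes of -0.07 in set 1 and -0.32 in set 2, and 36 lay above the set median in both sets against 2 below it in both. Among random lists matched on level their medians were at percentiles 100.0 and 93.3, so set 2 lay inside the central 95%, with a median close to that of all genes. Among other noncoding RNAs, chosen outside the rule, Rpph1, the RNA of ribonuclease P, fell by 0.88 (adjusted p = 0.0172), while Rmrp had a log2 fold change of -0.35 and Malat1 of -0.20.

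For the noncoding host genes, the level trends of the sets are argued against by the random lists matched on level. Among these the class median was at percentile 0 in both sets. After removal of the trends it was again at percentile 0, which adds little, since the lists already shared the level of the class. A lower yield of all long noncoding RNA is argued against as well, since 121 noncoding genes that host no small nucleolar RNA lay at percentiles 99.5 and 82.5. For reads from intronic small nucleolar RNAs or unspliced host RNA, the test set beforehand assumed that they would lower the 208 protein-coding hosts too. The percentiles of those hosts were 0 in set 1 and 69.5 in set 2, so that test, which needed both sets, did not decide. Taken by set, which was done afterwards, protein-coding hosts were below matched random lists in set 1 and not in set 2. The share of such reads was not measured and may differ between coding and noncoding hosts, so this explanation stays open in both sets. A response of these genes to loss of Chd1 stays a hypothesis, found and tested on the same libraries.

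The ratios of single genes were hardly correlated between the sets, and low values may account for part of this. Pearson r was 0.367 in the highest decile of genes and 0.116 in the lowest, a difference of 0.252, consistent with measurement noise of low genes, although r in most deciles between them was below that of the lowest. The opposite level trends were not the main reason, since r across all genes was 0.0842 after their removal. A difference between the 2 sets' cells stays open.

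Y-linked genes had values in both libraries of set 2, with Eif2s3y at 27.4 FPKM in the control and 20.2 in the Chd1-null library, and were not analysed in set 1.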
